A study of Brachypodium distachyon with 8 samples.

How the data were processed

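Small RNAs were sequenced from leaves of Brachypodium distachyon Bd21, a diploid inbred line of a model grass. There were 8 libraries, 1 per condition: unstressed plants, salt for 48 h, cold for 6 h and 24 h, heat in air for 1 h and 3 h, and heat by immersion in water for 1 h and 3 h. Per the labels' protocols, cold was 4 °C, heat was 42 °C, plants were otherwise grown at 22 °C, and for salt the soil was soaked with 300 mM NaCl. The labels' protocols name 2 Illumina small RNA library kits without tying either to a library, and sequencing on the Genome Analyzer II. Small RNAs of 15 to 40 nt were selected, per the series' design text.

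The deposited values are whole-number counts, called raw in the file headers, of small RNA reads per 3' UTR locus and read length. A locus here is 1 transcript identifier. In the deposited count files the header cells do not line up with the columns, and the length was read from the column whose values run from 15 to 41. Per the submitters' processing notes, CASAVA, Bowtie 0.12.7 and bedtools 2.10.0 were used, with no role or order given. The genome build, the annotation, the treatment of reads that map to several places and the use of strand are not given in the sources used here. A read that lies in several transcripts of a gene, or in near-identical copies, can therefore have been counted more than once.

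The deposited counts cover only the 3' UTR part of each library, so their totals are not the depth of sequencing. Totals ranged from 1730029 reads under salt to 4622303 after heat in air for 1 h. The files held 30815 identifiers from 24118 genes, and 4267 genes had more than 1 identifier. A locus entered the comparisons with 40 or more reads summed over the 8 libraries, which 18191 identifiers from 13130 genes had. No identifier could be joined to a gene name: 0 of the 24118 genes matched the 31335 genes of the RefSeq table for assembly Brachypodium_distachyon_v3.0, and the files do not pair identifiers with names. No gene functions or coordinates are therefore given.

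Libraries were scaled by the trimmed mean of log ratios (TMM) to the unstressed library, trimming 30% of log ratios and 5% of mean levels. The calculation was written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and was checked against edgeR 4.0.16, which gave the same scaling to within rounding. Figures were drawn with matplotlib 3.10.9. For each locus the ratio of scaled reads in 2 libraries was computed with an exact (Clopper-Pearson) 95% interval of the conditional binomial share. A locus was counted as higher or lower where the whole interval lay beyond 2-fold. For cold, heat in air and heat in water this had to hold at both times. Against 0 reads the fold was set against a floor of 3 counts in that library and is written with the words at least. It is not the lower end of the 95% interval, which lies lower. For Bradi1g08120.1 after 6 h of cold that end was 8.58-fold, against 10.6-fold with the floor. Shares of reads have exact (Clopper-Pearson) 95% intervals. Intervals and floors cover counting error only, because amplified reads are not independent molecules. With 1 library per condition no difference has a replicate check, each comparison is between 2 libraries and not between conditions, and no p-values are given.

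These rules were fixed before the data were examined, as was the rule for the loci named in the text. That rule took, for each kind of stress, the 10 loci in each direction with the interval bound farthest from no change, the 3 in each direction for each of the 5 direct comparisons between stressed libraries, and the 10 loci with the highest mean share of reads. Because no names could be joined, 2 loci per direction are printed for each stress and 1 per direction for each direct comparison. Gene lists fixed in advance were not run, since they needed gene descriptions.

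Each locus was also given a leading length class, the class with the highest mean share of its reads: 15 to 19, 20 to 23, 24, or 25 to 41 nt. This was added after the lengths were seen. The mean ran over the libraries with reads at the locus, including those compared. The class is therefore not independent of the change, and matching on reads does not remove this. The share of a list led by a class was set beside 10000 random lists of the same size, matched on mean scaled reads in 10 bins. Random lists drew identifiers as separate units, although identifiers of a gene can share reads. For overlaps of lists that share the unstressed library, 20 sets of unchanged libraries were simulated, and the overlap of independent lists was computed.

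The interval rule was tested on simulated data: all 18191 loci in each of 12 comparisons, 200 of them changed by 4-fold or 8-fold. Counts were drawn with counting (Poisson) error only, around 1 rate per locus pooled from the 2 libraries. Of the 4-fold changes, 16.7% were recovered for salt against unstressed, the lowest share, and 58.9% for heat in air at 3 h against 1 h, the highest. Of the 8-fold changes, 43.4% were recovered for heat in water at 1 h against unstressed and 94.6% for heat in air at 3 h against 1 h, again the extremes. Among loci with 40 or more reads in the 2 libraries, 4-fold changes were recovered in 52.4% for salt against unstressed to 87.7% for cold at 24 h against 6 h. At most 4 unchanged loci were called in a comparison, and 0 changed loci were called in the wrong direction. Apart from the changed loci, the 2 simulated libraries had the same composition. These counts therefore do not test errors from variation between plants. Nor do they test scaling across the difference in abundant loci between the unstressed and stressed libraries. Where each read was counted as 2, up to 175 unchanged loci were called, in heat in water at 1 h against unstressed.

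Alternatives were scaling by total reads or by the median of ratios over the 12846 loci with a read in every library, no count filter, a filter of 200 reads, an interval beyond 4-fold, reads of 20 to 24 nt, and leaving out the 10 most abundant loci. Counts halved and rounded up, 1 identifier per gene, other stressed libraries in place of the unstressed one, and leaving out the 100 most abundant loci were added after seeing the data. The reads of those other stressed libraries were pooled, with TMM scaling to heat in air at 3 h. A locus changed alike in them tends to drop out of that comparison, so its loss there does not count against the call. Counts of distinct sequences, reads at a unique place and the share of sense reads need sequences, positions or strands and were not analysed here.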

Results

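The study profiled small RNAs in Brachypodium leaves to ask how their populations change under abiotic stress. The counts analysed here are reads of 15 to 41 nt at 3' UTRs, the untranslated ends of transcripts, in 8 libraries of 1 condition each. Total 3' UTR reads were 3642238 in the unstressed library, 1730029 under salt, 4178296 and 2497143 after 6 h and 24 h of cold, 4622303 and 4027943 after 1 h and 3 h of heat in air, and 1942169 and 3461750 after 1 h and 3 h of heat in water. Reads were listed at 15765 loci in the unstressed library and at 20883 to 26825 loci in the stressed libraries. No condition was replicated, so every difference below is between libraries and its interval covers counting error only.

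The share of reads held by the 10 most abundant loci was highest in the unstressed library, at 89.9%. It was 38.9% after 24 h of cold, the lowest share, 49.6% under salt, and 56.2% to 71.3% in the 5 other stressed libraries, highest after 1 h of heat in water. Bradi4g27190.1 held 13.1% to 26.2% of reads in every library. Bradi1g05790.1 held 44.0% of reads in the unstressed library (95% interval 43.9% to 44.0%), 27.1% after 6 h of cold (27.0% to 27.1%), and 5.88% to 10.3% in the other 6 libraries. Bradi5g10760.1 held 11.4% of unstressed reads, of which 97.8% were 16 nt long, and 0.751% after 6 h of cold. Bradi5g00200.1 held a smaller share of unstressed reads, 1.71%, than of the reads of stressed libraries, 5.44% to 14.1%. Under TMM scaling it was 0.544 and 0.503 times the unstressed level after 6 h and 24 h of cold, and 1.00 to 1.51 times in the 5 other stressed libraries, so its direction in cold depended on the scaling. Bradi2g13080.1 and Bradi3g27270.1 held 11.7% and 11.6% of reads after 1 h of heat in air and 16.9% and 16.7% after 1 h of heat in water, mostly of 30 and 31 nt, against 0.956% and 0.937% in the unstressed library. Their counts over libraries and lengths were nearly identical, and up to 98.6% of the reads can be shared, so they cannot be treated as separate loci. Reads they share would count at both, in the totals and in the shares given here.

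**Figure D1:**
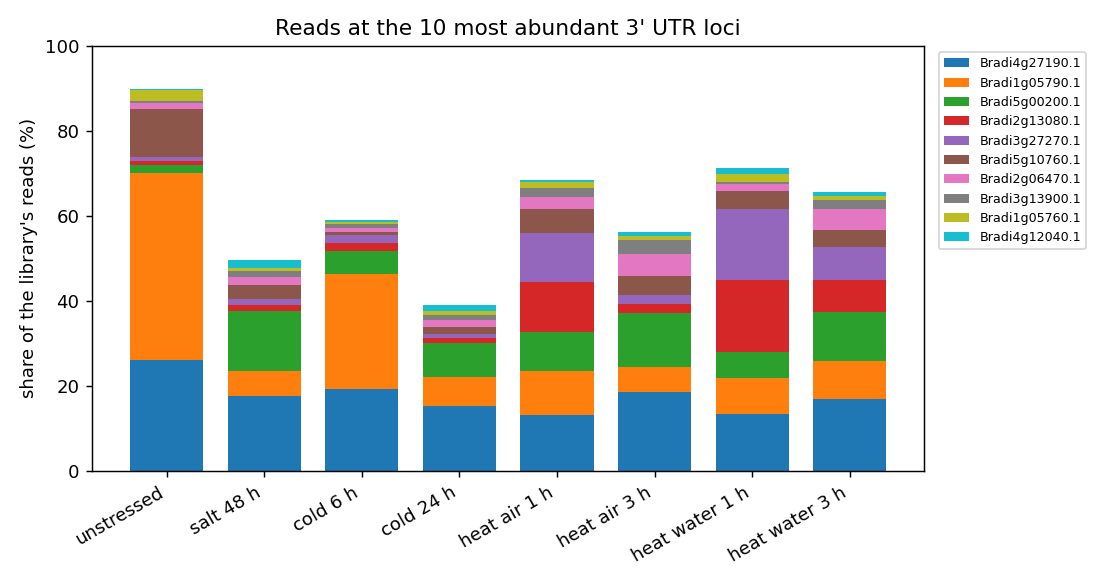
Stacked bars of the share of each library's 3' UTR reads (%, vertical axis) at the 10 most abundant loci, with 1 library per bar and no replicates. The unstressed bar reaches 89.9% and the bar for 24 h of cold 38.9%.

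In plants, 21 nt small RNAs include most microRNAs and 24 nt small RNAs are mainly the short interfering RNAs of RNA-directed DNA methylation. Over all 3' UTR reads, the ratio of 24 nt to 21 nt reads was 0.538 in the unstressed library (95% interval 0.534 to 0.542), the only library below 1. It was 1.94 under salt (1.93 to 1.96), 2.36 after 6 h of cold (2.35 to 2.37) and 3.303 after 24 h of cold (3.29 to 3.32). It was 1.86 (1.85 to 1.87) and 2.40 (2.39 to 2.41) after 1 h and 3 h of heat in air, and 1.90 (1.89 to 1.92) and 1.57 (1.57 to 1.58) after 1 h and 3 h of heat in water. Outside the 10 most abundant loci the ratio was 1.86 in the unstressed library and 2.37 to 4.21 in stressed libraries, still lowest without stress and highest after 24 h of cold. The 21 nt share outside these loci was highest without stress, at 12.9%, against 8.23% to 12.6% in stressed libraries. There, 24 nt was the commonest length in all 8 libraries. Its share was 42.5% (42.4% to 42.5%) and 43.3% (43.2% to 43.4%) after 6 h and 24 h of cold, 33.3% or less after heat, 27.0% under salt and 24.0% (23.8% to 24.1%) without stress. Outside the 100 most abundant loci the cold libraries were still highest, at 50.8% and 51.3%. The unstressed share of 38.3% (38.1% to 38.5%) was above salt at 35.3% and 3 h of heat in water at 33.8%. It was close to 1 h of heat in air at 38.2% (38.1% to 38.3%). Outside those 100 loci the 21 nt share was 18.2% without stress and 9.03% to 13.4% in stressed libraries.

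**Figure D2:**
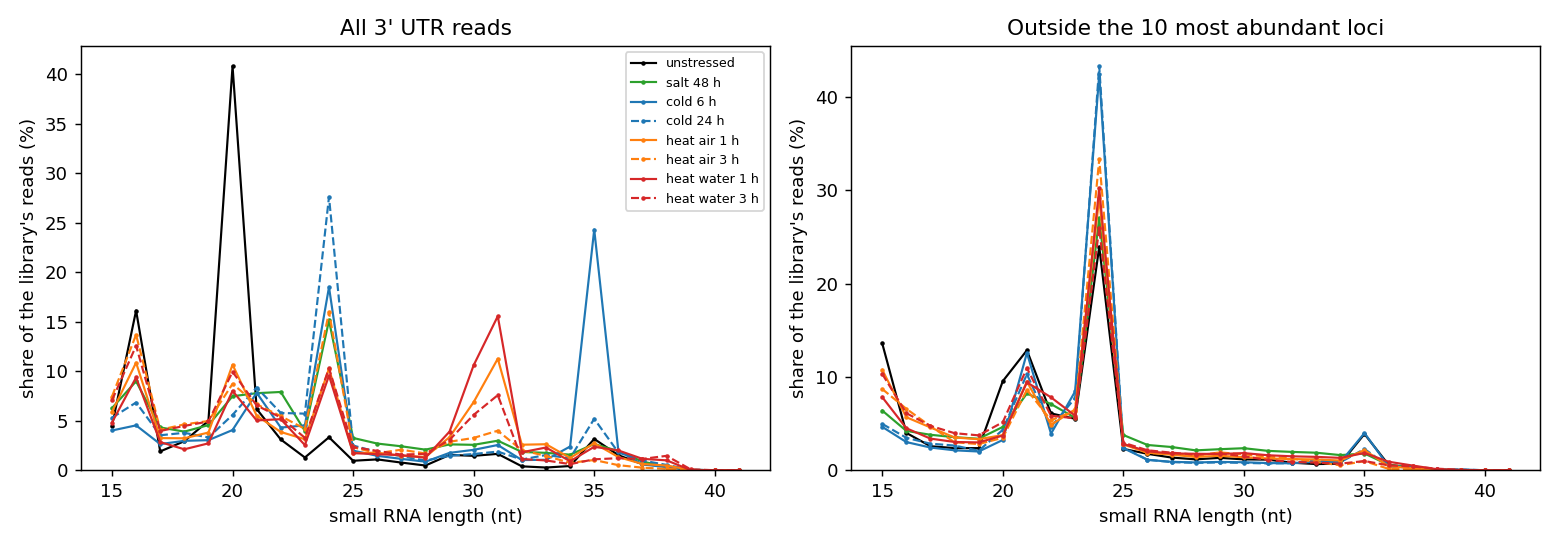
Share of each library's 3' UTR reads (%, vertical axes) by small RNA length in nt (horizontal axes), over all loci on the left and outside the 10 most abundant loci on the right. Each line is 1 library. Over all loci 20 nt was the commonest length in the unstressed library, at 40.8% of reads, and 35 nt after 6 h of cold; on the right 24 nt was the commonest length in all 8 libraries.

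The lengths that stood out over all loci came largely from few loci. Bradi1g05790.1 held 1304216 of the 1487611 reads of 20 nt in the unstressed library and 933044 of the 1016444 reads of 35 nt after 6 h of cold. At Bradi1g05790.1 the commonest length was 20 nt in the unstressed library, at 81.4% of the locus's reads, and in the 4 heat libraries, at 57.7% to 69.8%. In cold it was 35 nt, at 82.5% of the reads after 6 h and 47.0% after 24 h, with 20 nt at 0.849% after 6 h and 11.03% after 24 h. Under salt 20 nt made up 33.1% and 35 nt 16.9%. Reads of 30 and 31 nt, which were 3.11% of all unstressed reads, were 18.2% after 1 h of heat in air and 26.2% after 1 h of heat in water, and 2.65% and 3.45% there once the 10 most abundant loci were left out. The shares over all loci include both Bradi2g13080.1 and Bradi3g27270.1, so reads shared by that pair would raise them.

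**Figure D3:**
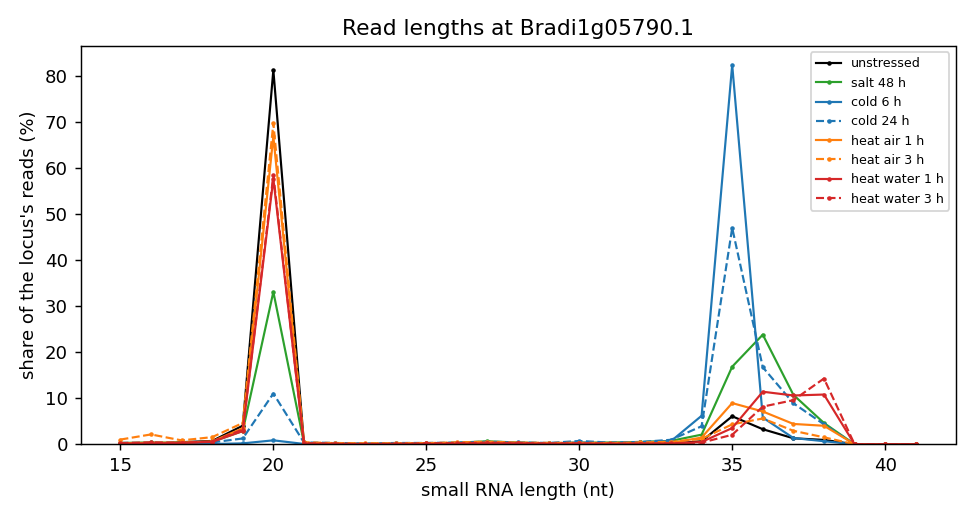
Share of the reads at Bradi1g05790.1 (%, vertical axis) by length in nt (horizontal axis), with 1 line per library. The unstressed and heat lines peak at 20 nt and the cold lines at 35 nt, where 6 h of cold reaches 82.5%.

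The concentration of unstressed reads in few loci makes every comparison with that library depend on scaling. Scaling by the trimmed mean of log ratios made the stressed libraries 3.61 to 9.30 times larger, relative to the unstressed one, than their totals did, a shift of 1.85 to 3.22 on the log2 scale. Under total scaling the median locus with at least 40 reads in the 2 libraries was above the unstressed library by 1.79 to 3.46 on the log2 scale. Changes below are relative to the trimmed mean, and the counts under total scaling stand beside them. A fold against the unstressed library is 3.61 to 9.30 times larger under total scaling where the locus was higher, and smaller by that factor where it was lower.

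Cold was compared with no stress at 6 h and 24 h. Of 18191 loci, 128 (92 genes) were higher and 398 (282 genes) lower at both times. Bradi1g03900.1 was 14.1-fold higher at 6 h (95% interval 11.1 to 18.3, 6347 against 67 reads) and 22.9-fold higher at 24 h (18.0 to 29.5, 9657 reads). Bradi1g08120.1 had 214 and 210 reads in cold and 0 without stress, at least 10.6-fold and 11.1-fold higher. Bradi5g10760.1, one of the most abundant loci, was 88.8-fold lower at 6 h (87.7 to 89.8) and 61.9-fold lower at 24 h (61.3 to 62.6), and Bradi1g15900.1 was 39.1-fold (37.6 to 40.7) and 58.9-fold (56.2 to 61.8) lower. Under total scaling Bradi1g03900.1 was 83.1-fold and 213-fold higher, Bradi5g10760.1 15.1-fold and 6.66-fold lower, and Bradi1g15900.1 6.66-fold and 6.33-fold lower. Loci led by 24 nt reads made up 67 of the 128 higher loci, 52.3% against a median of 60.2% in matched random lists (percentile 2.78), and loci led by 25 to 41 nt reads 21, 16.4% against 9.38%. Loci led by 24 nt reads were 79 of the 398 lower loci, 19.8% against 55.8%. Loci led by 15 to 19 nt reads made up 167 of the 398 lower loci, 42.0% against 18.3%, those led by 20 to 23 nt reads 91, 22.9% against 14.3%, and those led by 25 to 41 nt reads 61, 15.3% against 11.3%. With the salt and heat libraries in place of the unstressed one, 139 loci were higher and 826 lower, and these included 40 of the 128 and 72 of the 398. Under total scaling 8952 loci were higher and 10 lower, so that 99.9% of changed loci were higher in place of 24.33%. With counts halved 46 were higher and 225 lower, with an interval beyond 4-fold 18 and 121, and with reads of 20 to 24 nt alone 73 were higher and 284 lower.

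Heat in air was compared with no stress at 1 h and 3 h. At both times 310 loci (208 genes) were higher and 284 (211 genes) lower. The 2 higher loci ranked first by the weaker of their 2 times had 0 reads without stress. Bradi1g66470.1 had 3037 and 5047 reads, at least 199.6-fold and 257-fold higher, and Bradi5g02040.1 had 2728 and 3601, at least 179-fold and 184-fold higher. In cold and salt, Bradi1g66470.1 had 16 to 34 reads and Bradi5g02040.1 had 2 to 11. Bradi4g29450.1 was lower, with 2 and 6 reads against 102 (259-fold, 69.8 to 2164, and 111-fold, 49.3 to 309.9), as was Bradi4g07590.1, with 6 and 10 reads against 128 (108-fold, 48.4 to 300.3, and 83.7-fold, 44.0 to 179). Under total scaling Bradi4g29450.1 was 64.4-fold and 18.6-fold lower and Bradi4g07590.1 26.9-fold and 14.0-fold lower. Most of the higher loci were led by short reads of 15 to 19 nt, 176 of 310 or 56.8% against 15.8% in matched random lists, and 91 were led by 25 to 41 nt reads, 29.4% against 10.0%. Where a locus had 0 unstressed reads, its class came from the stressed libraries alone. Loci led by 24 nt reads were 33 of 310, 10.6% against 59.0%, and those led by 20 to 23 nt reads 10, 3.23% against 14.8%. Among the lower loci 105 of 284 were led by 20 to 23 nt reads, 37.0% against 14.8%, and 69 by 15 to 19 nt reads, 24.296% against 16.5%. Loci led by 24 nt reads were fewer than in matched lists there too, 85 of 284 or 29.9% against 58.5%. With the cold and salt libraries in place of the unstressed one, 488 loci were higher and 215 lower, and these included 201 of the 310 higher but 34 of the 284 lower loci. Of those 284, 182 were also lower under cold and 208 under salt, which limits what that comparison can keep. Under total scaling 6336 loci were higher and 18 lower, 99.7% higher in place of 52.2%. With reads of 20 to 24 nt alone 115 were higher and 206 lower, 35.8% higher, with counts halved 164 were higher and 196 lower, 45.6% higher, and beyond 4-fold 129 were higher and 92 lower.

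Heat in water, the same temperature given by immersion, also gave 310 higher loci (205 genes), with 275 lower (202 genes) at both times. The 2 higher loci ranked first by the weaker of their 2 times were the same as for heat in air. Bradi1g66470.1 had 1303 and 1994 reads, at least 227-fold and 156-fold higher, and Bradi5g02040.1 had 1317 and 1890, at least 229-fold and 148-fold higher. These folds were set against a floor, so they do not order the loci by their change. At 3 h Bradi1g68440.1 and Bradi2g02410.1 had more reads, 3585 and 3366 against 0. Bradi4g07590.1 had 0 reads at 1 h against 128, at least 81.8-fold lower, and 8 at 3 h, 68.1-fold lower (33.5 to 161). Bradi1g05790.1 was 18.6-fold lower at 1 h (18.5 to 18.7) and 22.4-fold lower at 3 h (22.3 to 22.5). Under total scaling Bradi4g07590.1 was 15.1-fold lower at 3 h, and Bradi1g05790.1 5.16-fold and 4.97-fold lower. Again 176 of the 310 higher loci were led by 15 to 19 nt reads, 56.8% against 16.5% in matched lists, 93 by 25 to 41 nt reads, 30% against 10.6%, 22 by 20 to 23 nt reads, 7.10% against 15.2%, and 19 by 24 nt reads, 6.13% against 57.7%. Of the 275 lower loci, 97 were led by 24 nt reads, 35.3% against 58.5%, 76 by 15 to 19 nt reads, 27.6% against 16.7%, and 71 by 20 to 23 nt reads, 25.8% against 14.5%. With the cold and salt libraries in place of the unstressed one, 527 loci were higher and 198 lower, and these included 179 of the 310 higher but 30 of the 275 lower loci. Of those 275, 162 were also lower under cold and 204 under salt. Under total scaling 4293 loci were higher and 13 lower, 99.7% higher in place of 53.0%. With reads of 20 to 24 nt alone 115 were higher and 183 lower, 38.6% higher, with counts halved 153 and 178, 46.2% higher, and beyond 4-fold 133 and 76.

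Salt was sampled only at 48 h, so its lists rest on 1 stressed library and are not held to a second time. There, 764 loci (501 genes) were higher and 628 (453 genes) lower. The 2 higher loci ranked first, Bradi3g44640.2 and Bradi3g44640.1, are transcripts of the same gene that can share reads, with 462 and 451 reads against 0, at least 47.8-fold and 46.6-fold higher. Bradi3g44720.1 and Bradi4g07590.1 had 0 reads under salt against 150 and 128, at least 161-fold and 138-fold lower, and at least 23.5-fold and 20.02-fold lower under total scaling. Of the higher loci 354 were led by 15 to 19 nt reads, 46.3% against 22.5% in matched lists, and 276 by 25 to 41 nt reads, 36.1% against 13.9%. Loci led by 24 nt reads were 65 of the higher loci, 8.51% against 49.6%, and 262 of the lower ones, 41.7% against 56.2%. Among the 628 lower loci 174 were led by 15 to 19 nt reads, 27.7% against 18.3%, 141 by 20 to 23 nt reads, 22.5% against 14.3%, and 51 by 25 to 41 nt reads, 8.12% against 11.1%. With the cold and heat libraries in place of the unstressed one, 638 loci were higher and 732 lower, and these included 269 of the 764 and 168 of the 628. Under total scaling 11787 were higher and 26 lower, 99.8% higher in place of 54.9%. With counts halved 260 were higher and 327 lower, 44.3% higher, with reads of 20 to 24 nt alone 282 and 339, 45.4% higher, beyond 4-fold 162 and 149, with a filter of 200 reads 546 and 410, and with 1 identifier per gene 528 and 386.

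**Figure D4:**
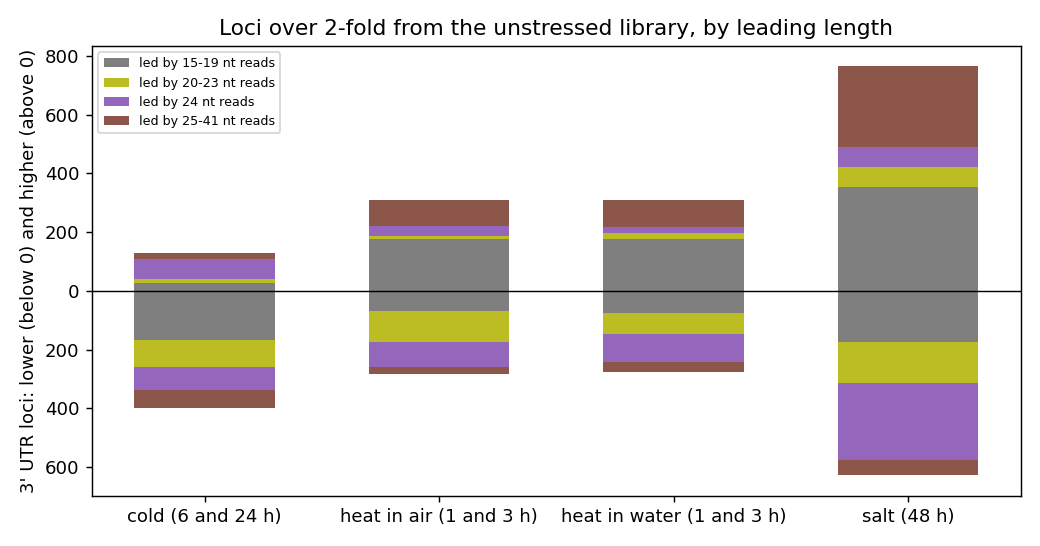
Number of 3' UTR loci (vertical axis) whose whole 95% interval lay beyond 2-fold from the unstressed library, higher above 0 and lower below 0, for each stress. Colours give the length class that led the locus. Of the 310 higher loci under each form of heat, 176 were led by 15 to 19 nt reads, 56.8% against 15.8% (air) and 16.5% (water) in matched random lists. Under cold 67 of 128 were led by 24 nt reads, 52.3% and so below the 60.2% of matched lists.

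The lists of different stresses overlapped. Heat in air and heat in water shared 177 higher loci, where independent lists would share 5.28 and simulated unchanged libraries at most 1, and 167 lower loci, against 4.29 and 1. With the longer salt lists, of 628 lower and 764 higher loci, heat in air and heat in water shared 208 and 204 lower loci. Independent lists of those sizes would share 9.80 and 9.49. They shared 120 and 140 higher loci with salt, against 13.0 in each case. Longer lists overlap more by their size, so these counts do not rank how alike the stresses were. Cold and salt shared 257 lower loci, against 13.7 and 0, and 41 higher ones, against 5.38 and 1. All 4 stresses shared 16 higher loci (14 genes) and 126 lower loci (94 genes). Libraries simulated without change give few calls, so their small overlap does not show what a shared reference library alone would give. The figure for independent lists ignores that library too. All lists were drawn against the same unstressed library, which cannot be split. Part of the excess may come from that library, and how much was not determined.

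The 2 times of each stress were compared directly. Cold at 24 h differed from 6 h at 903 loci, 506 higher and 397 lower. Bradi3g42050.1 had 999 reads against 4 (265-fold, 103 to 976), and Bradi3g15040.1 had 0 against 65, at least 20.4-fold lower. Heat in air at 3 h differed from 1 h at 819 loci, 354 higher and 465 lower. Bradi5g00720.1 had 825 reads against 29 (22.1-fold higher, 15.3 to 33.2), while Bradi3g42050.1 had 0 against 198, at least 85.1-fold lower. Heat in water at 3 h differed from 1 h at 767 loci, 394 higher and 373 lower. Bradi2g42650.1 had 346 reads against 2 (77.9-fold higher, 21.4 to 646), and Bradi5g17700.1 had 23 against 357 (34.5-fold lower, 22.6 to 55.1). Under total scaling 1348 loci were higher and 138 lower for cold, 1141 and 209 for heat in air, and 721 and 248 for heat in water. With counts halved the 3 comparisons gave 512, 471 and 371 loci, and beyond 4-fold 220, 185 and 136.

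Heat in water and heat in air were compared at matched times. At 1 h, water differed from air at 694 loci, 362 higher in water and 332 lower. Bradi1g67680.1 had 388 reads in water and 43 in air (23.9-fold higher, 17.4 to 33.5), and Bradi2g42650.1 had 2 against 477 (90.1-fold lower, 24.8 to 746). At 3 h, 916 loci differed, 574 higher in water and 342 lower. Bradi2g01920.1 had 42 reads in water and 0 in air, at least 21.5-fold higher, and Bradi1g01760.1 had 0 against 204, at least 44.3-fold lower. The direction of the balance depended on scaling: under total scaling 263 loci were higher and 434 lower at 1 h, and 277 and 782 at 3 h. With counts halved the comparisons gave 309 and 491 loci, and beyond 4-fold 111 and 183.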

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

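The loci in this part were singled out after their values were seen. They were chosen for opposite changes from the same unstressed library, so a difference between the 2 times follows from the choice, and no independent test of it was run. At 3 loci the 2 cold libraries differed from the unstressed library in opposite directions, each beyond 2-fold. Bradi2g54580.1 was higher at 6 h and lower at 24 h, with 622 and 46 reads against 30 without stress. Bradi3g42050.1 was lower and then higher, with 4 and 999 reads against 24, as was Bradi3g53130.1, with 8 and 332 against 10. Opposite directions from the unstressed library depended on the scaling. Under total scaling Bradi3g42050.1 stayed beyond 2-fold both ways (-2.77 and 5.94 on the log2 scale), Bradi3g53130.1 kept its directions with -0.51 and 5.61, and Bradi2g54580.1 was higher at both times, by 4.18 and 1.18.

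In the heat in air libraries 4 loci were higher at 1 h and lower at 3 h than in the unstressed library. They were Bradi2g01920.1 (144 and 0 reads against 4), Bradi2g01940.1 (2577 and 72 against 135), and the read-sharing pair Bradi2g13080.1 (542069 and 89182 against 34833) and Bradi3g27270.1 (537743 and 87872 against 34136). Under total scaling the interval was beyond 2-fold both ways at 0 of the 4. Bradi2g01940.1 kept its directions, with log2 values of 3.92 and -1.04, and Bradi2g01920.1 was higher at 1 h, by 4.83, with 0 reads at 3 h. The pair was above the unstressed library at 3 h too, by 1.22 and 1.23.

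At 4 loci the 2 heat in water libraries differed from the unstressed library in opposite directions. Bradi1g09120.1 (269 and 66 reads against 49) and Bradi3g46780.1 (300 and 51 against 42) were higher at 1 h and lower at 3 h. Bradi2g15310.1 (10 and 313 against 24) and Bradi2g42650.1 (2 and 346 against 26) were lower at 1 h and higher at 3 h. Under total scaling the interval was beyond 2-fold both ways at 0 of these 4. Bradi2g15310.1 and Bradi2g42650.1 kept their directions, with log2 values of -0.35 and 3.79 and of -2.79 and 3.82, while Bradi1g09120.1 and Bradi3g46780.1 were above the unstressed library at 3 h too, by 0.51 and 0.36.

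Reads longer than the selected range of 15 to 40 nt occurred in 1 library: 20 reads of 41 nt at Bradi1g30650.1 after 3 h of heat in water, with 0 in the unstressed library.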

How the results depend on the processing

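Halving counts, keeping 1 identifier per gene, replacing the unstressed library and leaving out 100 loci were chosen after seeing the data. All 13 counts stayed within 1.5 times the main value under the median of ratios and without a filter. Among up to 38 printed ratios of loci that the rule ranked by their change, 0 reversed under any of the 8 settings in which they were recomputed and had a value. Their printed changes were larger than the shift of 1.85 to 3.22 on the log2 scale between TMM and total scaling, so this follows from the ranking and says nothing about the other loci. Of 31 further ratios, of the loci with opposite directions at 2 times, 5 reversed under total reads, becoming positive on the log2 scale against the unstressed library: 1.18 for Bradi2g54580.1 after 24 h of cold, 1.22 and 1.23 for Bradi2g13080.1 and Bradi3g27270.1 after 3 h of heat in air, and 0.51 and 0.36 for Bradi1g09120.1 and Bradi3g46780.1 after 3 h of heat in water. Total scaling moves all loci of a library by the same amount, so these reversals follow from that shift and from values smaller than it. Under the 7 other settings 0 of those with a value reversed. Of 62 further ratios against the unstressed library, of the 10 loci that the rule named for their share of reads, 25 reversed under total reads by the same shift. On the log2 scale Bradi5g00200.1 went to 1.68 and 2.23 after 6 h and 24 h of cold. Under salt and after 6 h and 24 h of cold, Bradi2g13080.1 went to 0.65, 0.97 and 0.25, Bradi3g27270.1 to 0.55, 0.94 and 0.18, Bradi3g13900.1 to 1.53, 0.91 and 1.42, and Bradi4g12040.1 to 2.40, 0.64 and 1.87. Bradi4g12040.1 also went to 0.60 and 1.51 after 1 h and 3 h of heat in air and 1.21 after 3 h of heat in water, and Bradi3g13900.1 to 0.24 and 2.07 after 1 h and 3 h of heat in water. Bradi2g06470.1 went to 0.42 under salt, 0.11 after 24 h of cold, 0.91 and 1.91 in heat in air and 0.22 and 1.85 in heat in water. With reads of 20 to 24 nt 6 reversed: Bradi2g06470.1 to 0.52 under salt, 0.0190 after 6 h of cold, 0.39 after 1 h of heat in air and 0.92 after 3 h of heat in water, and Bradi3g13900.1 to -0.26 and 0.39 after 3 h of heat in air and in water. Without a filter Bradi3g13900.1 went to 0.00454 after 3 h of heat in water. After 1 h of heat in water Bradi5g00200.1, at 0.00594, went to -0.0121 under the median of ratios and -0.0333 with a 200-read filter.

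For these changes, apart from total reads, and those below the cause was not tested, except that a 4-fold bound counts fewer loci by construction. A 200-read filter and 1 identifier per gene test fewer loci but also rescale the libraries. With that filter 501 of the 546 higher loci under salt were in the main list. Halving counts widens intervals, while rounding up and rescaling can shift ratios. Counts are given as higher and lower for cold, heat in air, heat in water and salt, then as differing for cold times, air times, water times, water against air at 1 h and at 3 h.

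Total reads gave 8952 and 10 for cold, 6336 and 18 for heat in air, 4293 and 13 for heat in water, 11787 and 26 for salt, 1486 for cold times and 1350 for air times. A 200-read filter gave 546 and 410 for salt, 573 for cold times, 510 for water times and 574 for water against air at 3 h. A 4-fold bound gave 18 and 121, 129 and 92, 133 and 76, 162 and 149, then 220, 185, 136, 111 and 183. Reads of 20 to 24 nt gave 73 and 284 for cold, 115 and 206 for heat in air, 115 and 183 for heat in water, 282 and 339 for salt, 532 for air times and 582 for water against air at 3 h. Halved counts gave 46 and 225 for cold, 164 and 196 for heat in air, 153 and 178 for heat in water, 260 and 327 for salt, then 512, 471, 371, 309 and 491. With 1 identifier per gene salt gave 528 and 386. Other stressed libraries in place of the unstressed one gave 139 and 826 for cold, 488 and 215 for heat in air and 527 and 198 for heat in water.

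The 24 nt to 21 nt ratio without the 10 most abundant loci, and without the 100 most abundant, was 1.86 and 2.11 in the unstressed library, 3.28 and 3.78 under salt, 3.38 and 3.79 after 6 h of cold, and 4.21 and 4.81 after 24 h. It was 3.08 and 3.56 after 1 h of heat in air, 3.87 and 4.60 after 3 h, 3.20 and 3.79 after 1 h of heat in water, and 2.37 and 2.90 after 3 h.

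No paired analysis was possible because each condition has 1 library, so no replicate was left out either. Distinct sequences, reads at a unique place, the share of sense reads and the gene lists were not run. Outside the 10 most abundant loci the unstressed library had 367188 reads, the fewest of the 8 libraries. In the self-test, 16.7% to 36.1% of 4-fold changes were recovered in comparisons with that library and 34.4% to 58.9% in direct comparisons of stressed libraries. These ranges overlap, and the part of depth in them was not separated.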

Other observations

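All tests weighed in this part were chosen after the results were seen. Of the 394 loci higher in water at 3 h than at 1 h, 185 were led by 15 to 19 nt reads and 66 by 24 nt reads, while of the 373 lower ones 84 were led by 15 to 19 nt and 181 by 24 nt reads. In air the loci higher and lower at 3 h than at 1 h were closer, with 140 of 354 and 180 of 465 led by 15 to 19 nt reads and 106 and 133 by 24 nt reads. Of all tested loci 30.4% were led by 15 to 19 nt and 40.5% by 24 nt reads, and no test of a difference between these lists was run. In water against air at 3 h, 98 of the 574 higher loci and 147 of the 342 lower ones were led by 24 nt reads. At 1 h the order was the other way, with 144 of 362 higher and 90 of 332 lower loci led by 24 nt reads.

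At the 2102 loci with 20 or more reads in every library, the median share of 24 nt reads was lowest without stress, at 47.8%. It was 53.3% and 53.6% after 1 h of heat in air and 3 h of heat in water, 55.7% under salt, 59.3% after 3 h of heat in air, 59.5% after 6 h of cold, 60% after 1 h of heat in water and 61.2% after 24 h of cold. On these shared loci cold did not stand apart from heat in water at 1 h.

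The unstressed library stood apart in how few loci held its reads. The 10 most abundant loci accounted for much of the gap but not all of it: without them the median ratio of the TMM size to the total over the 7 stressed libraries was 1.38, against a range of 3.61 to 9.30 with them. Lower depth alone is argued against, because with every library thinned to 367188 reads outside those loci, the unstressed library listed 15755 loci, 0.793 times the 19862 of the stressed library with fewest. A different library kit cannot be told apart from the absence of stress, since 2 kits were used and 0 libraries have a kit named in their own labels. The unstressed library also had the lowest share of even counts, 51.4% against 61.0% to 67.8% in the stressed ones. Whether that difference bears on the gap was not tested. A narrower small RNA population in leaves without stress stays open and untested.

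The share of 24 nt reads, pooled over loci, was higher in both cold libraries than in the 6 others. A few abundant loci are argued against as the source, because outside the 100 most abundant loci the lower cold share was still 9.26 percentage points above the highest other share. That share too is pooled, so it does not address which of the remaining loci held the reads. At the 2102 shared loci the median after 6 h of cold, 59.5%, was not above the 60% after 1 h of heat in water. Outside the 10 loci the lower cold ratio of 24 to 21 nt was 0.873 times the highest other. That of 24 to 20 to 23 nt was 1.08 times. Both ratios lie within 20 to 24 nt, so they cannot show fewer reads of other lengths. TMM-scaled 24 nt reads there were 29758 and 28788 in cold, against 20027 to 24726 in the 6 others. Those of 15 to 19 nt were 9984 and 10654, against 15880 to 25152. Those of 25 to 41 nt were 10562 and 9046, against 12582 to 19372. Under that scaling 24 nt reads were thus higher and these other lengths lower. Such levels depend on the scaling, and the part of each was not separated. An effect of cold itself stays open and untested.

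In 8 of 8 libraries the count 2 was commoner than 1. The excess ran from 1.05 times in the unstressed library to 2.65 times after 3 h of heat in air. Even values made up 51.4% of values in the unstressed library and 61.0% to 67.8% in the stressed ones. If reads were entered more than once, intervals from the counts would be too narrow. If that differed between libraries, ratios to the unstressed library could shift too, which halving all counts alike does not address. Neither is shown here. Listing of most loci more than once is argued against, since 3.24% of the 17261 identifiers with 20 or more values had only even values. It is not argued against for those 560 identifiers, which had even values throughout. The share of 2 among values of 1 or 2 differed by -0.280 percentage points between genes with several identifiers and genes with 1. This cannot decide whether transcripts of a gene share reads, since a shared read may add 1 at each identifier without making a 2. Entry of reads of 1 strand a second time cannot be told apart from other causes, because 0 columns give a strand. The share of 2 was 75.4% for reads of 26 to 38 nt and 61.7% for reads of 20 to 25 nt, and no biological explanation was tested.

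A hypothesis from these data is that 3' UTR loci led by 15 to 19 nt reads may vary more between libraries than loci led by 24 nt reads. At matched mean reads, the share of loci that differed between the 2 times of a stress was 3.13 times higher for loci led by 15 to 19 nt reads in cold, 3.91 times in heat in air and 2.78 times in heat in water. These ratios use the same calls that prompted the hypothesis and are not an independent test of it. The contrast was not particular to that class: against loci led by 24 nt reads the share was also 2.53, 2.15 and 2.05 times higher for loci led by 20 to 23 nt reads, and 3.12, 2.65 and 2.00 times for those led by 25 to 41 nt reads. It can as well be read as fewer differences at loci led by 24 nt reads, and a response to time is not separated from variation between single libraries.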
